A study of Mus musculus with 6 samples.

How the data were processed

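Colon RNA of mice aged 56 days was measured in 6 libraries, 3 labelled WT and 3 labelled Il10 knockout. Per the labels' protocols, libraries were made from total RNA with an NEBNext Ultra RNA kit and sequenced on an Illumina Genome Analyzer IIx. The submitters' processing notes name Bowtie 0.12.2 and the genome builds hg38 and mm8, with no role given for either build. The authors deposited 1 table of FPKM values for 54532 genes, with gene coordinates, lengths and biotypes per the file headers; the counting tool, its strand setting and its handling of reads that map to several places are not given in the sources used here. Of the 54409 gene identifiers found in GENCODE mouse release M21, 53499 (98.3%) had identical coordinates there, so coordinates are given as GRCm38, the build of that annotation, although the notes name other builds.

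Each deposited FPKM value multiplied by the gene length was a whole multiple of 1 step per library, within a tolerance of 0.01, for 100% of values above 0. Reads recovered this way totalled 13107941 to 15797928 per library, and 27114 genes had no read in any library. The library size implied by the FPKM values, divided by a median-of-ratios size factor computed from the recovered reads, was the same in every library and equalled the geometric mean of the recovered totals; this scaling was worked out from the values and no source states it. The implied size was 0.836 to 1.23 times the recovered total. Floors of 3 reads and read numbers cover counting error only.

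Groups and replicate numbers came from sample titles. Before averaging, libraries were compared in pairs: chi-square per gene on the recovered reads was 67.4 or more for every pair, so no library was a repeat of another. Values were taken as log2(FPKM + 1) for the 12668 genes with a mean FPKM of at least 1 over the 6 libraries, and tested with limma 3.58.1 (lmFit, eBayes with the mean trend, not robust) in R 4.3.3, with no replicate block, Benjamini-Hochberg adjustment and a threshold of 0.05. Of the 40 gene lists fixed before the data were examined, the 37 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over lists, and again with an estimated correlation and with fry. Genes within 10 Mb of Il10 were set against all other tested genes with Fisher's exact test. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

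The genes named were chosen by a rule fixed before the data were examined. Il10 came first. Next came, among called genes whose groups did not overlap, leaving out predicted genes and immunoglobulin or T cell receptor variable segments, the 10 with the highest and the 10 with the lowest log2 fold change, filled up to 10 per direction by the smallest unadjusted p and described as not past the threshold. Up to 4 members with the smallest p were taken from each list called by camera. Other list members and genes quoted per library were chosen after their values were seen.

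The fit was tested on data simulated for this comparison from its 12668 genes and fitted spread, in 10 runs with 200 changed genes each. It called 4.0% of genes changed by a log2 fold of 1, 70.6% at 2, 90.2% at 3 and 98.0% at 5. These rates hold for simulated groups with the same spread, while the real WT libraries differed among themselves more than the knockout ones. In the data 167 genes were higher and 86 lower by a log2 fold of 2 or more, and 23 genes were called. The rates may thus overstate the power of this comparison. The mean share of false calls was 6.92%, above the nominal 5%, over calls that leave out the genes of the shifted list. A shifted list was called by camera in 10 of 10 runs and an unshifted one in 0; the simulated genes varied independently of each other, so these runs do not test the preset correlation.

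Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter, mean FPKM of at least 0.1 or 5, rescaling by TMM factors (trims of 0.3 and 0.05), quantile normalization, TPM, eBayes without the trend or robust, weights per library, a replicate block, and leaving out each library. Scalings and left-out libraries kept the genes of the main filter, apart from genes left with no reads. Fits chosen after seeing the data were voom on the recovered reads, leaving out WT libraries 2 and 3, and the smooth muscle list mean as a covariate. Leaving out WT libraries 2 and 3 left only WT library 1, so the calls of that fit hold no spread between WT libraries. They enter the tallies over the alternatives. Planned tests on deposited counts were not run, since the table holds FPKM.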

Results

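Colon RNA of mice aged 56 days was sequenced in 3 libraries labelled WT and 3 libraries labelled Il10 knockout, all on a C57BL/6 background. Interleukin 10 is a cytokine that restrains immune responses, and mice without it are widely used as a model of chronic colitis. The comparison asks how the colon transcriptome differs between the genotypes. The values were FPKM (fragments relative to gene length and library size, as scaled by the authors). Reads recovered from them amounted to 13107941, 15797928 and 13747377 in WT libraries 1 to 3 and to 14262740, 14651559 and 14235679 in Il10 knockout libraries 1 to 3. The libraries labelled WT differed among themselves more than those labelled Il10 knockout: across genes, Pearson's r of log2 values was 0.795 to 0.864 between WT pairs and 0.935 to 0.961 between knockout pairs, where genes are not independent replicates. Between the labels r was 0.747 to 0.910. WT libraries 1 and 2 correlated more with each library labelled knockout (0.872 to 0.910 and 0.829 to 0.887) than with each other (0.826), and WT library 1 also more than with WT library 3 (0.864), so the libraries labelled WT did not group by label. No source used here says that the libraries of a group came from separate mice, so p-values measure the spread between these libraries. Log2 fold changes are knockout minus WT on the log2(FPKM + 1) scale, which understates the change of low genes.

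Il10 itself had more RNA in every library labelled Il10 knockout, the opposite of a loss of its RNA. Il10 (ENSMUSG00000016529; GRCm38 chromosome 1, 131019845 to 131024974, plus strand) was at 0.757, 0.173 and 0.177 FPKM in WT libraries 1 to 3, and at 13.8, 10.6 and 14.5 FPKM in the libraries labelled Il10 knockout 1 to 3. These values rested on 22 reads over the WT libraries and 755 reads over those labelled knockout. The log2 fold change was 3.36 (SE 0.25) with an adjusted p of 0.0092 in limma, and an exact two-sided permutation test of the 3 against 3 libraries gave p = 0.1, the smallest it allows. The value counts reads over the whole gene, and neither the allele nor its deleted part is given in the sources used here, so it does not check the labels exon by exon. The adjusted p was above 0.05 when WT library 3 (0.0618), Il10 knockout library 2 (0.059) or Il10 knockout library 3 (0.0671) was left out, and it lay between 0.00243 and 0.241 over the alternatives. Whether the targeted allele is still transcribed was not tested, so this gene neither bears out nor contradicts the labels. Every direction below rests on the labels as given.

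Among 12668 genes, 23 were higher and 0 were lower in the libraries labelled Il10 knockout (limma with Benjamini-Hochberg adjustment at 0.05). They were led by S100a8 and S100a9, the subunits of the neutrophil protein calprotectin. S100a8 averaged 702 ± 437 FPKM in the libraries labelled knockout against 0.104 ± 0.112 in WT (SD, n = 3), with a log2 fold change of 9.10 (SE 0.51, adjusted p = 0.00226). S100a9 averaged 356 FPKM against 0 reads in all 3 WT libraries, which makes it at least 2621-fold higher against a floor of 3 reads over the WT group (adjusted p = 0.000486). Reg3g, an antibacterial lectin, had a log2 fold change of 7.60 (SE 0.92, adjusted p = 0.049). Nos2, the inducible nitric oxide synthase, had one of 6.35 (SE 0.72, adjusted p = 0.0381). Lrg1, a secreted acute-phase glycoprotein, had one of 6.04 (SE 0.54, adjusted p = 0.0157). The cornified envelope gene Sprr2h reached 49.4 ± 8.55 FPKM against 0.29 ± 0.369, and the surface protein gene Plet1 reached 451 ± 207 against 8.99 ± 6.30 (SD, n = 3). Plet1 overlaps the antisense gene Plet1os, also called, and no strand setting is given, so reads of the pair cannot be assigned to either. Gml, Gml2 and Myl7 completed the 10 named genes, with log2 fold changes of 4.40, 3.72 and 3.82. Gml2 was at 0 reads in WT and at least 260-fold higher, and it overlaps Cyp11b1 on the other strand. Gml and Gml2 are related in sequence, as are members of the Sprr2 and Reg3 families, so their separate values are uncertain.

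**Figure D1:**
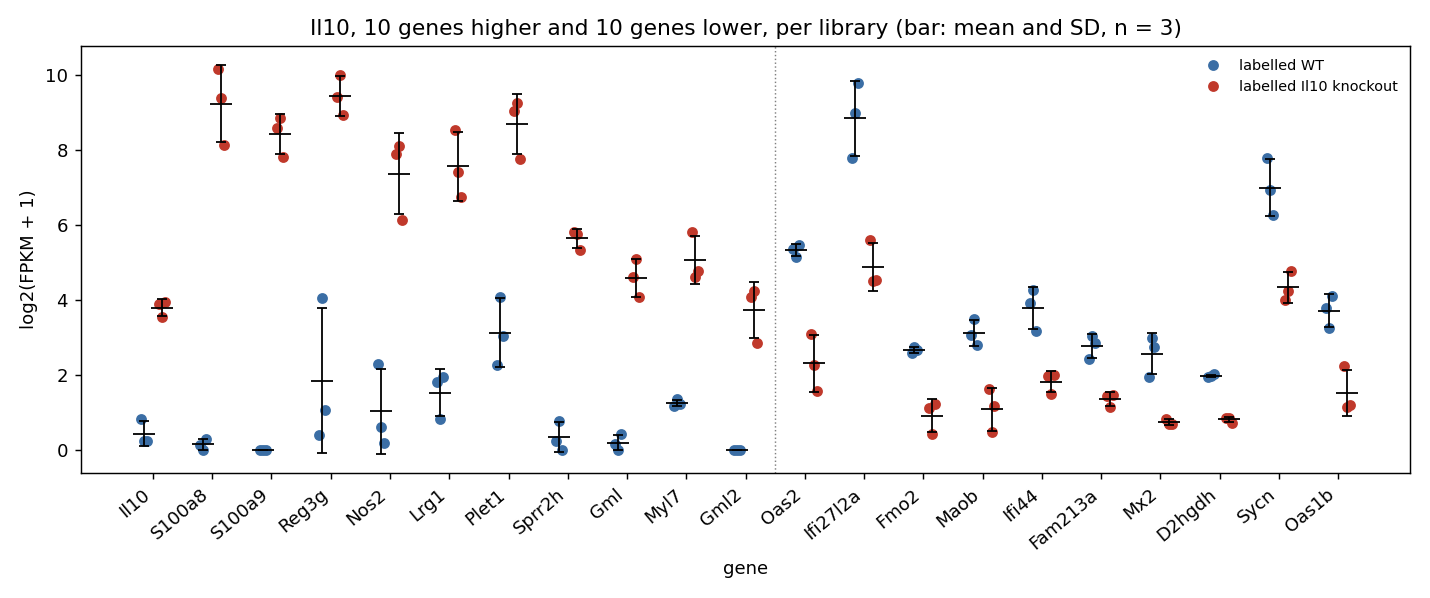
Log2(FPKM + 1) of Il10, 10 genes higher and 10 genes lower in the libraries labelled Il10 knockout, with 1 point per library and bars for the mean and SD (n = 3). Il10 and the 10 genes left of the dotted line passed the adjusted threshold, and the 10 genes to its right did not.

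The count of 23 depended on which libraries were included. It was 12 without WT library 1, 26 without WT library 2, 5 without WT library 3, 29 without Il10 knockout library 1, 4 without Il10 knockout library 2 and 7 without Il10 knockout library 3. Of the 26 genes 16 were among the 23, and of the 29 genes 12 were. Leaving out WT libraries 2 and 3 together, a setting chosen after seeing the data, left only WT library 1 on the WT side. No count is given for that fit, which holds no spread between WT libraries. Over all alternatives the count lay between 1, with the smooth muscle list mean as a covariate, and 331, with a weight per library. Those weights were estimated from the same libraries, at 2.76, 0.198 and 0.465 for WT libraries 1 to 3. For Il10 knockout libraries 1 to 3 they were 1.01, 2.62 and 1.49. The WT side of that fit thus rested mostly on WT library 1. At an unadjusted p under 0.05, 778 genes were higher and 510 lower, against 633 expected by chance over both directions. Another grouping of the same libraries, WT libraries 1 and 3 with Il10 knockout library 3 against the rest, gave 1907 such genes against 1288 for the labels. All 3 libraries of one label lay above all 3 of the other for 16.7% of genes against 10% by chance.

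No gene passed the threshold in the lower direction; by limma 510 had an unadjusted p under 0.05. Lower genes called numbered 94 with array weights, 3 without WT library 2 and 2 without Il10 knockout library 1, while voom on the recovered reads called 2 genes in all and none of them lower. The 94 came from the weighted fit, whose WT side rested mostly on WT library 1. The 10 genes with the smallest p among those whose groups did not overlap included 5 interferon-stimulated genes. Oas2, a sensor of double-stranded RNA, was at 39.3 ± 4.41 FPKM in WT and at 1.97 to 7.55 FPKM in the libraries labelled knockout (log2 fold change -3.02, SE 0.40, adjusted p = 0.0615). Ifi27l2a was at 533 ± 329 FPKM in WT (SD, n = 3) with a log2 fold change of -3.97 (SE 0.59, adjusted p = 0.0752). Ifi44, Mx2 and Oas1b had log2 fold changes of -1.96, -1.82 and -2.20, and the annotation in the file lists Mx2 and Oas1b as polymorphic pseudogenes. The other 5 were Fmo2 and Maob, which encode flavin-dependent oxidases, Fam213a, D2hgdh and Sycn, with log2 fold changes of -1.75, -2.04, -1.42, -1.17 and -2.65. Sycn overlaps Samd4b on the other strand.

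The fixed lists of antimicrobial and neutrophil genes were the highest of all lists in the libraries labelled Il10 knockout. Of 23 measured epithelial antimicrobial and acute-phase genes, 22 had higher values and 1 a lower one, with a median log2 fold change of 2.87 (quartiles 1.83 and 5.19). Over all genes 5 were called higher, and adjusted over the list alone 16 were. Besides those above, Reg3b had a log2 fold change of 9.61 (adjusted p = 0.0687) and Duox2, an epithelial oxidase, one of 2.74 (adjusted p = 0.0752). Of 16 listed neutrophil markers, 11 passed the filter on mean FPKM. All 11 had higher values, with 2 called over all genes and 10 adjusted over the list alone. Those at 0 reads in WT passed the filter through the libraries labelled knockout alone. Their median was 3.02, or 5.70 with the 5 genes at 0 reads in one group set at their lower bound. Those bounds are FPKM ratios without a pseudocount, while the other members kept theirs, so 5.70 mixes both scales. The median was 5.03 with a pseudocount of 0.1 and 7.26 with 0.01. It was 4.69 at a mean FPKM of at least 5 and 6.39 with voom on the recovered reads. Lower values came with no filter (2.05), a mean FPKM of at least 0.1 (2.30) and array weights (2.325). They also came without Il10 knockout library 2 (2.41) or WT library 2 (2.56). S100a8 and S100a9 stand in both lists. Camera with the preset correlation called both lists higher (adjusted p = 6.53e-21 and 1.65e-16), and neither call held with an estimated correlation (adjusted p = 0.185 for both). Fry, which asks whether a list's own genes move one way on balance, called these 2 lists (adjusted p = 0.0048 for both).

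Of 25 measured cytokines and chemokines of colitis, 23 had higher values, with a median of 1.21. The neutrophil attractants Cxcl1 and Cxcl2 were called over all genes (log2 fold changes 3.34 and 3.54, adjusted p = 0.0157 and 0.024), and 7 were called adjusted over the list alone. Tnf had a log2 fold change of 2.98 (adjusted p = 0.0586), and Il17a was at 0 reads in WT and at 0.812, 4.34 and 2.04 FPKM in the libraries labelled knockout 1 to 3 (adjusted p = 0.299). All 12 genes of the IL-10 receptor and signalling list had higher values (median 0.58), with 0 called over all genes by limma, 6 at an unadjusted p under 0.05 and 4 adjusted over the list alone, among them Socs3 with a log2 fold change of 2.99 (adjusted p = 0.069). Camera called both lists with the preset correlation (adjusted p = 2.54e-10 and 1.54e-05) and neither with an estimated correlation (adjusted p = 0.459 for both). Without WT libraries 2 and 3 the cytokine median was 0.28. That list was called with medians of 0.57 with array weights and 0.53 with the smooth muscle covariate.

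The interferon lists went opposite ways. Of 31 measured interferon-gamma response and GBP genes, 30 had higher values in the libraries labelled Il10 knockout (median 1.25), 0 were called over all genes by limma, 18 had an unadjusted p under 0.05, and Ido1 and Socs1 were called adjusted over the list alone, with log2 fold changes of 5.07 and 2.07. The list mean of WT library 1, at 4.53, lay near those of the libraries labelled knockout, at 4.75 to 5.33, and the list median was 0.81 without WT library 3, 0.75 with array weights, 0.42 without WT libraries 2 and 3 and 0.47 with the smooth muscle covariate, where 7 of the 31 had lower values. Of 27 type I interferon-stimulated genes, 26 had lower values (median -1.37), 0 were called over all genes, 15 had an unadjusted p under 0.05 and the same number were called adjusted over the list alone. Isg15 was at 223, 775 and 173 FPKM in WT libraries 1 to 3 and at 114, 63.1 and 65.7 FPKM in the libraries labelled knockout. Ifit2 was the 1 member with a positive log2 fold change, 1.06 (adjusted p = 0.664). Of 11 MHC class II presentation genes, 10 had higher values (median 1.66), 0 were called over all genes, 7 had an unadjusted p under 0.05 and 6 were called adjusted over the list alone, Cd74 with a log2 fold change of 2.16 (adjusted p = 0.306). The MHC class II list was not called with array weights (median 0.86, camera adjusted p = 0.168). Its median was 0.48 without WT libraries 2 and 3, and 0.91 with the smooth muscle covariate (camera adjusted p = 0.00983). Camera called the 3 lists with the preset correlation (adjusted p = 3.38e-11, 1.65e-16 and 7.45e-05). With an estimated correlation the adjusted p was 0.607, 0.459 and 0.607. GBP, Oas, Ifit and Ifi27 genes have near-identical relatives, and single values may share reads.

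**Figure D2:**
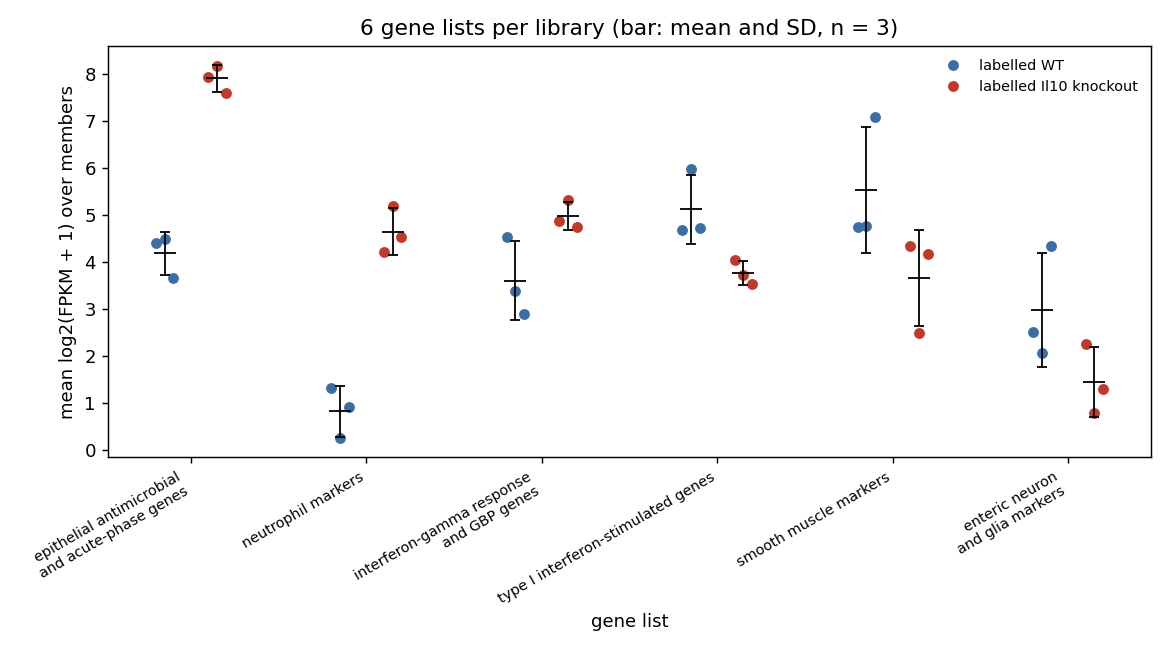
Mean log2(FPKM + 1) over the tested members of 6 gene lists, with 1 point per library and bars for the mean and SD (n = 3). The smooth muscle mean of WT library 3, at 7.09, lies apart from the other libraries labelled WT, at 4.75 and 4.78.

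Muscle and neuron genes had lower values in the libraries labelled Il10 knockout, with WT library 3 far above the rest and Il10 knockout library 2 the lowest. All 18 measured smooth muscle markers had lower values (median -2.02), 0 were called over all genes or adjusted over the list alone by limma, and 5 had an unadjusted p under 0.05. Acta2, smooth muscle actin, was at 458, 418 and 2561 FPKM in WT libraries 1 to 3 and at 312, 57.2 and 263 FPKM in the libraries labelled knockout. Of 21 enteric neuron and glia markers, 19 had lower values (median -1.59), with 0 called either way and 11 at an unadjusted p under 0.05. The smooth muscle list mean was 4.75, 4.78 and 7.09 in WT libraries 1 to 3 and 4.33, 2.48 and 4.17 in the libraries labelled knockout, and that of neurons and glia was 2.51, 2.06 and 4.35 against 2.25, 0.787 and 1.29. Without WT library 3 the medians were -1.24 for smooth muscle (18 of 18 lower) and -0.95 for neurons and glia (19 of 21 lower), and without Il10 knockout library 2 they were -1.35 and -1.32. Without WT libraries 2 and 3 the smooth muscle median was -1.11. The neuron and glia median was -2.55 with a pseudocount of 0.1, -2.75 with 0.01 and -2.83 with voom on the recovered reads. With the smooth muscle covariate the neuron and glia list was not called (median -0.21, camera adjusted p = 0.369). Camera called both lists lower with the preset correlation (adjusted p = 1.37e-10 and 1.22e-09), and neither with an estimated correlation (adjusted p = 0.607 for both). Mitochondrial genes took 43.4% of the reads of WT library 3, 20.3% and 11.7% in WT libraries 1 and 2, and 22.0%, 8.61% and 15.5% in the libraries labelled knockout.

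In all, camera with the preset correlation called 14 lists higher and 6 lower out of 37, and none of them held with an estimated correlation (adjusted p of 0.185 or more). The other lists called higher were cytosolic ribosomal proteins (median 0.46), endoplasmic reticulum stress (0.47), cell cycle genes (0.32), plasma cell and immunoglobulin markers (0.84), epithelial identity and junctions (0.67), T cell and NK cell markers (0.46), nuclear-encoded oxidative phosphorylation (0.36) and goblet cell markers (0.58). Yet the highest list mean of any library was that of WT library 1 for T cells (2.61) and plasma cells (5.85). It was that of WT library 2 for epithelial identity (7.50) and oxidative phosphorylation (7.21). For the rest of these lists it was that of a library labelled knockout. The other lists called lower were enteroendocrine markers (-0.85), xenobiotic and steroid metabolism (-0.58) and adipocyte markers (-0.79). With an estimated correlation their adjusted p lay between 0.459 and 0.834. Over the 21 alternatives, camera with the preset correlation called the antimicrobial, neutrophil, interferon-gamma, type I interferon and IL-10 signalling lists each time, and in the same direction. All alternatives reused the same libraries and the preset correlation of 0.01, while the correlations estimated for these lists were 0.128 to 0.585. Other splits of the libraries also called 12 to 25 lists. Tallies of calls, here and below, therefore show how calls move with the settings and add no independent support.

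The enteroendocrine, smooth muscle and neuron lists were called lower in 20 of the 21, all but the fit with the smooth muscle covariate, which removes the smooth muscle difference by its construction. The endoplasmic reticulum stress and cytokine lists were called higher in 20, all but the fit without WT libraries 2 and 3. Each of the other called lists lost its call with a left-out library, another scaling or filter, or a weight per library. T cells were not called without WT library 2 (median 0.33, adjusted p = 0.306) or 3 (0.20, adjusted p = 0.358), at a mean FPKM of at least 5 (0.74, adjusted p = 0.218) or with array weights (-0.02, adjusted p = 0.587), and their median was 0.78 without WT library 1, 0.80 and 0.83 with pseudocounts of 0.1 and 0.01, 0.69 with TPM and 0.78 with voom. Plasma cells were not called without WT library 2 (0.43, adjusted p = 0.358) or 3 (0.52, adjusted p = 0.199), without Il10 knockout library 1 (0.67, adjusted p = 0.0858) or with array weights (-0.61, adjusted p = 0.237), and their median was 1.93 without WT library 1. Epithelial identity was not called without WT library 3 (0.17, adjusted p = 0.659) or Il10 knockout library 1 (0.54, adjusted p = 0.0519), and its median was 1.17 without WT library 2. Goblet cells were not called without WT library 2 (0.13, adjusted p = 0.959), without Il10 knockout library 3 (0.34, adjusted p = 0.0717), at a mean FPKM of at least 5 (0.58, adjusted p = 0.148), with quantile normalization (0.40, adjusted p = 0.0848) or with array weights (0.14, adjusted p = 0.736). Cell cycle genes were not called without WT library 2 (-0.02, adjusted p = 0.306), without Il10 knockout library 3 (0.19, adjusted p = 0.178), at a mean FPKM of at least 5 (0.41, adjusted p = 0.134) or with array weights (-0.03, adjusted p = 0.347), and their median was 0.60 without WT library 1 and 0.49 without Il10 knockout library 1. Oxidative phosphorylation was not called without WT library 1 (0.29, adjusted p = 0.131) or 3 (0.04, adjusted p = 0.872), without Il10 knockout library 1 (0.25, adjusted p = 0.27), at a mean FPKM of at least 5 (0.36, adjusted p = 0.134) or with quantile normalization (0.05, adjusted p = 0.692), and its median was 0.71 without WT library 2. Ribosomal proteins were not called with quantile normalization (0.11, adjusted p = 0.157), under which endoplasmic reticulum stress, still called, had a median of 0.23. Xenobiotic metabolism was not called without WT library 2, where its median changed sign (0.38, adjusted p = 0.821), or without Il10 knockout library 2 (-0.36, adjusted p = 0.0633). Its median was -1.16 without WT library 3, -0.97 without Il10 knockout library 1 and -0.37 without Il10 knockout library 3. Adipocytes were not called without WT library 2 (-0.77, adjusted p = 0.149) or with array weights (-0.53, adjusted p = 0.0523), and their median was -0.51 without Il10 knockout library 3. The enteroendocrine median was -1.27 without Il10 knockout library 1 and -0.50 with no filter, where the adipocyte median was -0.51. Medians of lists still called were 0.30 for ribosomal proteins and -0.35 for xenobiotic metabolism with array weights, and 0.37 for epithelial identity with quantile normalization.

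The settings without WT libraries 2 and 3 and with the smooth muscle covariate, both chosen after seeing the data, moved some of these lists and left others. Epithelial identity had a median of 0.70 without WT libraries 2 and 3, against 0.67 with all libraries. With the covariate, ribosomal proteins (0.44) and endoplasmic reticulum stress (0.42) hardly moved from 0.46 and 0.47. Without WT libraries 2 and 3, where WT library 1 stood alone, the medians of T cells (-0.27), plasma cells (-0.94) and cell cycle genes (-0.20) were negative. The medians were then -0.09 for goblet cells, 0.21 for ribosomal proteins and 0.37 for endoplasmic reticulum stress. For xenobiotic metabolism and adipocytes they were -0.23 and -0.48. With the smooth muscle list mean as a covariate the enteroendocrine list was not called (-0.15, adjusted p = 0.756); its members Cpe and Scg2 were highest in WT library 3, at 85.3 and 23.4 FPKM, and Scg2 also stands in the neuron list. The covariate also ended the calls of T cells (0.07, adjusted p = 0.869), plasma cells (0.57, adjusted p = 0.279), epithelial identity (-0.18, adjusted p = 0.369), goblet cells (0.39, adjusted p = 0.121), oxidative phosphorylation (-0.07, adjusted p = 0.634) and adipocytes (-0.67, adjusted p = 0.174), and the xenobiotic median was -1.08 with it.

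Not called were the lists of macrophages and monocytes (median 0.40), B cells (-0.02), colonocyte transport (0.28), tuft cells (-0.30), fatty acid oxidation (-0.22), cholesterol synthesis (0.23), fibroblasts (-0.50), endothelium (-0.10), small intestine (0.58), pancreas and liver (0.46), heat shock (-0.11) and circadian genes (-0.19). Stem and Wnt targets (0.03), immediate early genes (0.12) and mitochondrially encoded genes (-0.30) were also not called, and their medians changed sign under quantile normalization. The stem list had a positive median where camera pointed down, and the extracellular matrix list, not called, had a median of -0.49 and a mean of 0.01. Lists of mast cells, red blood cells and squamous skin had fewer than 5 measured members and were not tested. Several of these lists were called when 1 library was left out. Fatty acid oxidation was called higher without WT library 2 (0.54, adjusted p = 0.0268) and lower without WT library 1 (-0.50, adjusted p = 0.00692), WT library 3 (-0.56, adjusted p = 0.00198) or Il10 knockout library 1 (-0.44, adjusted p = 0.00939). B cells were called higher without WT library 1 (0.75, adjusted p = 0.0401) and lower without Il10 knockout library 1 (-0.74, adjusted p = 0.0255). Macrophages were called higher without WT library 1 (0.69, adjusted p = 0.00104) or Il10 knockout library 1 (0.75, adjusted p = 0.00333). Colonocyte transport was called higher without WT library 1 (0.61, adjusted p = 0.0408) or Il10 knockout library 3 (0.32, adjusted p = 0.0366), and cholesterol synthesis without WT library 2 (0.52, adjusted p = 0.00325) or Il10 knockout library 3 (0.39, adjusted p = 0.0181). Extracellular matrix was called lower without WT library 2 (-0.78, adjusted p = 0.00122) or Il10 knockout library 3 (-0.60, adjusted p = 0.00508). Heat shock genes were called lower without WT library 2 (-0.24, adjusted p = 0.0268) or Il10 knockout library 1 (-0.40, adjusted p = 0.00434), and mitochondrially encoded genes without Il10 knockout library 1 (-0.71, adjusted p = 0.0437). By contrast, camera called mitochondrially encoded genes higher with the smooth muscle covariate (1.17, adjusted p = 1.32e-09). Their median was also positive without WT library 3 (0.24) or Il10 knockout library 2 (0.29). Fibroblasts, just short of the threshold (adjusted p = 0.0518), were called lower in 12 of the 21 alternatives, among them those without WT library 1 (-0.65, adjusted p = 0.0498), WT library 2 (-0.58, adjusted p = 0.0066) or Il10 knockout library 3 (-0.47, adjusted p = 0.0483). Over all alternatives macrophages were called higher in 8, B cells higher in 1 and lower in 3, cholesterol synthesis higher in 7 and lower in 1, and heat shock genes lower in 8. The B cell median was -1.44 with array weights (camera adjusted p = 0.00183) and -1.57 without WT libraries 2 and 3. The lists of endothelium, small intestine, pancreas and liver, circadian genes, stem and Wnt targets and the neighbours of Il10 were called in none.

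**Figure D3:**
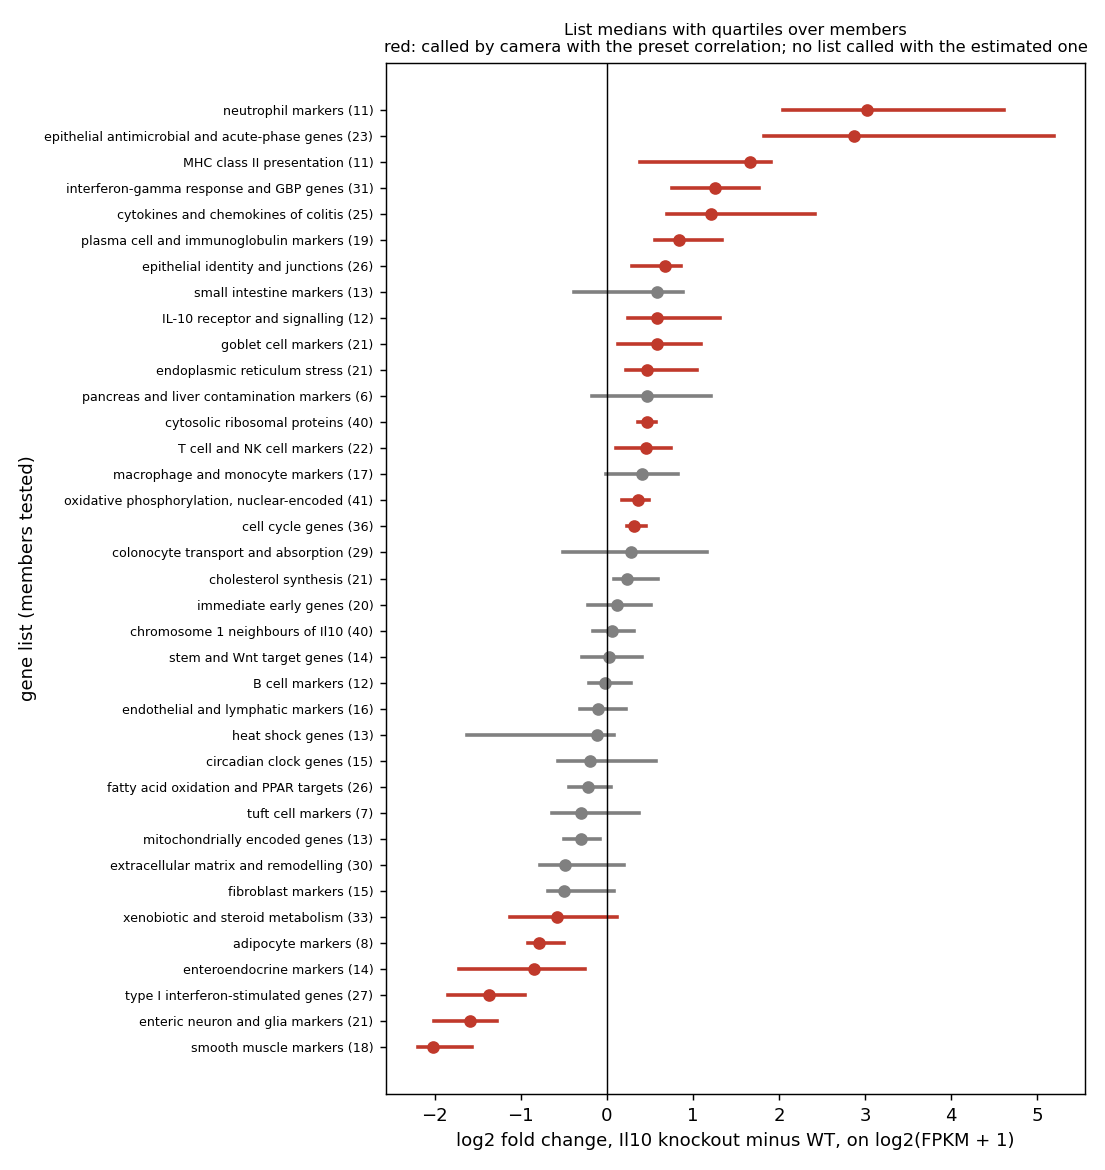
Median log2 fold change, knockout minus WT on the log2(FPKM + 1) scale, of 37 gene lists, with lines from the lower to the upper quartile of their members. Red lists were called by camera with the preset correlation, and none was called with an estimated one; the neutrophil median of 3.02 is the highest and the smooth muscle median of -2.02 the lowest.

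Genes beside Il10 were tested because a knockout allele can carry flanking sequence of another strain. Of 91 tested genes within 10 Mb of Il10, 0 were called by limma and 9 had an unadjusted p under 0.05, which is 9.89% against 10.2% of other genes. Fisher's exact test gave p = 1 for both, the median log2 fold change was 0.06, and camera gave p = 0.929. With 23 genes called among 12668, 0 among 91 neighbours was likely with or without flanking sequence of another strain. Camera asks for a shared direction, which such differences need not have. These tests thus show no excess of changed neighbours and do not exclude flanking sequence. For the shorter fixed list of neighbours, with 40 measured genes, camera gave an adjusted p of 0.473 and 1 gene was called adjusted over the list alone.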

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

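The fits without WT libraries 2 and 3, with the smooth muscle mean as a covariate and with voom were chosen after seeing the data. The planned count models (DESeq2, edgeR with RLE factors, no count filter) were not run, since the table holds FPKM. The cause of each move was not tested, and fits with libraries left out also had smaller groups. Of 1852 values of named genes other than Il10, 1715 kept direction and side of the threshold, 93 lost the call, 37 gained it and 7 changed sign. Most of these values could not lose a call, since only 13 of the 90 named genes, Il10 among them, were called at first. Of the called genes, Reg3g kept its call in 7 of the 21 alternatives, Nos2, Plet1 and Gml2 in 10 each, and S100a9 in 21.

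Genes called, 23 at first, numbered 9 with a pseudocount of 0.01, 4 with no filter, 46 with TPM, 331 with array weights, 2 with voom, 6 without WT libraries 2 and 3 and 1 with the covariate; genes higher numbered 9, 4, 44, 237, 2, 5 and 1. Leaving out 1 library gave 4 to 29 called, 4 to 27 higher and 0 to 3 lower. Genes lower, 0 at first, numbered 1 with a mean FPKM of at least 5, 1 with quantile normalization, 2 with TPM and 94 with array weights. All 23 genes were among the 331, from a fit whose WT side rested mostly on WT library 1. S100a9 was the 1 named gene called in all 21 alternatives. TPM moved the median of all genes by 0.106.

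Replicate numbers are shared by the groups but nothing says they pair mice. The numbers were therefore not taken as pairs, a choice made before the data were examined. Deviations of same-numbered libraries correlated at -0.149, 0.18 and 0.396. WT library 3 correlated best with its own number, and so did WT library 2, by a small margin (0.18 against 0.177 for Il10 knockout library 1). WT library 1 did not, so these values do not settle whether the numbers pair. With the replicate block 7 genes were called, 7 of them higher, all among the 23.

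The Il10 log2 fold change, 3.36, stayed positive. Its adjusted p was above 0.05 at 5.43 with a pseudocount of 0.01, 3.36 with no filter, 5.29 with voom and 3.36 with the covariate. Without WT libraries 2 and 3 the log2 fold change was 2.98. Without 1 library it lay between 3.27 and 3.56. Called lists, 20 at first, numbered 0 with an estimated correlation and 2 with fry, and 17 to 24 without 1 library. Called neighbours of Il10 on chromosome 1, 0 at first, numbered 1 with TPM, 1 with array weights and 0 to 1 without 1 library.

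Sign changes were Igha with array weights (-0.31) and without WT libraries 2 and 3 (-0.94), Cldn2 (-0.10) and Cdc20 (-0.0084) without WT libraries 2 and 3, and Rrm2 (-0.045), Cox5a (-0.30) and Fabp4 (0.11) with the covariate. None of these genes was called at first.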

Other observations

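Some cell type genes differed between single libraries rather than between labels; these genes were chosen after their values were seen. Cd79a, a B cell receptor component, was at 22.8 FPKM in WT library 1 and 30.6 FPKM in Il10 knockout library 1, and at 0.728 to 3.07 FPKM in the other 4. Car1, a carbonic anhydrase of colonocytes, was at 31511 FPKM in WT library 2, 117 and 456 FPKM in WT libraries 1 and 3, and 5716, 544 and 481 FPKM in the libraries labelled Il10 knockout 1 to 3. Cyp2c55 was at 4492 FPKM in WT library 2 and at 0.0319 to 449 FPKM elsewhere. Ctrb1, a pancreatic protease precursor, was at 45.7 FPKM in Il10 knockout library 3 and at 0 in the other 5.

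Of the tests below, those with the smooth muscle covariate on the interferon and neuron lists had their bounds set before the result was seen, and the others were chosen after it.

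Il10 RNA was higher in the libraries labelled Il10 knockout. An exchange of all labels, with the knockout mice being the inflamed ones, is argued against by the neutrophil median of 3.02, but no source used here gives the state of the tissue, so an exchange with inflamed WT mice stays open. A gain of macrophages, T cells, B cells and plasma cells that raised their listed genes evenly is argued against as the whole source of a log2 fold change of 3.36 (SE 0.25). The highest median of their lists was 0.84, and it was 1.93 for plasma cells without WT library 1. The median of a whole list cannot show a gain of only some of these cells, so that stays open. On the same scale as the Il10 value, the neutrophil median was 3.02 (quartiles 2.05 and 4.61), which leaves a gain of neutrophils open. With the genes at 0 reads in one group at their bound the median was 5.70. That value mixes in ratios without a pseudocount and cannot be set directly against 3.36. A candidate explanation that stays untested is RNA from a targeted allele that is still transcribed, which values per gene cannot show.

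Type I interferon-stimulated genes had lower values in the libraries labelled Il10 knockout, by a median of -1.37. Without WT library 2, the highest for this list, the median was -0.95 (quartiles -1.31 and -0.56), which argues against that library as the whole source. With the smooth muscle mean as a covariate it was -1.62 (quartiles -2.01 and -1.16), so adjusting for that mean did not remove the difference. The smooth muscle mean also differs between the labels, so this fit cannot exclude muscle share. A difference of genotype, or of housing or cohort that follows it, may lie behind the pattern and was not tested.

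Smooth muscle and neuron genes had lower values in the libraries labelled Il10 knockout. Without WT library 3 the smooth muscle median was -1.24 (quartiles -1.31 and -0.83) instead of -2.02, which argues against that library as the whole source. Much of the difference still lay in single libraries, as the list means of WT libraries 1 and 2 were 4.75 and 4.78 and those of Il10 knockout libraries 1 to 3 were 4.33, 2.48 and 4.17. With the smooth muscle mean as a covariate the neuron and glia median moved from -1.59 to -0.21 (quartiles -0.38 and 0.05), as 1 share of muscle layer setting both lists would give. The covariate also moved lists of other cells, enteroendocrine from -0.85 to -0.15 and epithelial identity from 0.67 to -0.18, while neutrophils kept 2.3. It differs between the labels too, so this fit cannot show that muscle layer is the source. Whether such a share, if present, came from dissection or from the tissue stays open.

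The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 23 genes and the highest other 0 (1 split as high, the real one). At an unadjusted p under 0.05 the real split gave 1288 genes and the highest other 1907 (2 splits as high, the real one included); that split puts WT libraries 1 and 3 with Il10 knockout library 3. The real split called 20 lists with the preset correlation, and the highest other called 25, with 4 of the 10 at 20 or more.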
